A study of Homo sapiens with 2 samples.

How the data were processed

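Total RNA of human leukocytes was extracted with silica columns, depleted of ribosomal RNA and made into strand-preserving sequencing libraries, per the labels' protocols. The 2 libraries used here are labelled Control and Experiment, with 1 library in each group. The treatment of the Experiment cells, and whether both libraries came from the same donor, are not given in the sources used here.

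The deposited table holds raw read counts per gene symbol, as whole numbers, with 1 column for each library. Per the submitters' processing notes, the reads were handled on genome build GRCh38 with tools that include STAR 2, Picard 1.126, bedtools 2.17.0, HTSeq 0.6.0, DESeq2 and R 3.1.1. The role and order of these tools, the strand setting of the counting and the annotation release are not given in the sources used here. Without the strand setting, counts of a gene and of an overlapping antisense gene cannot be told apart, and genes that overlap another gene or share sequence with a copy are uncertain. Each column was matched to its sample by the sample title that begins the column name, and no column was left over. The table has 59368 rows, of which 36809 held at least 1 count in either library.

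Biotypes and coordinates came from GENCODE release 29 on GRCh38. By symbol, 55822 rows (94.0%) were found there, with 99.2% of all counts, and 630 more received a biotype from a RefSeq gene table. A total of 106 symbols had several records in GENCODE, with 0.493% of counts, and were given no coordinates.

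Library sizes were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 1.07 for Control and 0.938 for Experiment. Genes with at least a normalised abundance of 1 CPM (counts scaled to library size) in either library were kept, which left 20214 genes, 13252 of them protein-coding. With 1 library per group no test between conditions was possible and no p-value was computed. For each gene, the ratio of Experiment to Control was taken with its exact 95% interval, from the conditional binomial (Clopper-Pearson) limits computed with scipy 1.17.1. A gene was counted as at least 2-fold higher or lower where its whole interval lay at or above a ratio of 2, or at or below 0.5. These intervals, and the detection floors below, cover counting error only, because each group had 1 library. They treat reads as independent, but reads amplified by PCR without molecular identifiers are not independent molecules. The intervals may therefore be too narrow even for counting error. They say how well the 2 libraries were compared and nothing of how much cells of one group vary.

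Depth sets the precision. For a gene with 100 counts over both libraries the interval ran from 0.662 to 1.52 times its ratio, and with 1000 counts from 0.881 to 1.14 times. A count of 0 allows a level of up to 0.184 CPM in Control and 0.151 CPM in Experiment, taken as 3 counts. No measured member of a gene list was at 0 in either library.

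Gene lists were assembled for 10 cell types and for pathways and RNA classes that fit activated leukocytes, 52 in all. Of these, 51 had at least 5 members past the filter and were scored by the median log2 ratio, with 0.5 counts added to each library. The median was placed among those of 10000 random lists of the same size, matched on mean abundance in 20 bins, and a list was said to stand apart at or below percentile 2.5 or at or above 97.5. At these limits 2.55 of 51 lists of unrelated genes would stand apart by chance. The lists used here share some genes, and genes of 1 cell type can move together. The number expected for them is therefore not known and can be higher. The percentile describes these 2 libraries only. The named genes are the 15 protein-coding genes with the highest and the 15 with the lowest ratio, ranked by the interval limit nearest to 1, among genes with at least 5 CPM in the library where they were higher. To these come up to 4 members of a list farthest from 1 in the direction of its median, up to 2 in the other direction, a set of common lead genes (IL1B, IL6, TNF, CXCL8, IFNG, CD69, FOS, JUN, HMOX1 and HSPA1A), and the 5 genes with most counts in each library. FCGR3B, CREB5, HEMGN, SNRPN, the named members of a second platelet list and the genes above the highest platelet marker were chosen outside this rule, after their values were seen. The lists, the naming rule, the filter and the alternative settings, except those said to be added later, were fixed before the data were examined. Genes whose level can tell persons apart, and a few others that the rule names, are not reported here.

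The steps were tested on simulated counts drawn with the abundance and depth of the Control and Experiment libraries, with 50 genes changed at each of 4 sizes. All 50 genes changed 8-fold and all 50 changed 4-fold were called past 2-fold, 96% of those changed 3-fold and 0 of those changed 1.5-fold. None (0) of 19555 unchanged genes was called, and 95.8% of their intervals held a ratio of 1. The simulated counts held counting error alone, with no variation between libraries. These figures therefore check the steps and give no rate of false calls for the real libraries. With random noise added to the simulated log2 ratios and fewer comparison lists, 6.5% of 200 random lists stood apart.

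Alternatives covered 3 other scalings (DESeq2 1.42.0 size factors, upper-quartile factors and total counts alone), the filter on low counts, library sizes without mitochondrial and structured RNAs, protein-coding genes alone, the fold and interval rule, the added count, the mean in place of the median, the pool and the limits of the random lists, and, added after seeing the data, the removal of platelet genes. Figures were drawn with matplotlib 3.10.9.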

Results

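The transcriptomes of human leukocytes were profiled by RNA sequencing after ribosomal RNA removal, to compare cells described as activated with cells described as not activated. The labels do not say which group held the activated cells. The comparison rests on 1 library labelled Control and 1 labelled Experiment, and no replicate check of any difference was possible. The Control library held 15266118 counts over 33419 genes and the Experiment library 21109646 counts over 33939 genes, so the second was 1.38 times deeper. All ratios below are Experiment over Control after TMM scaling, with 95% counting intervals.

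Platelet and mitochondrial transcripts were much higher in the Experiment library, transcripts of B cells, monocytes and cytotoxic lymphocytes were moderately higher, and neutrophil transcripts were lower. Of 19 platelet markers measured, 18 were more than 2-fold higher, with a median ratio of 4.21. Of 21 neutrophil markers, 13 were lower and 3 higher by more than counting error, with a median log2 ratio of -0.81. T cell markers, by contrast, had a median log2 ratio of -0.04 over 18 genes, with 5 higher and 8 lower. Chemokine transcripts were higher in 11 of 13 cases. Of 19 pro-inflammatory cytokines 11 were higher, among them IFNG, encoding interferon gamma, at 2.81 (2.32 to 3.41) and IL1B at 1.93 (1.89 to 1.98), and 5 were lower, and the list did not stand apart by its mean. Immediate early and NF-kB target genes did not stand apart from random lists, and interferon-stimulated genes did so, as lower, by their mean but not by their median.

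Over the 20214 genes that passed the filter, 987 (4.88%) had a ratio of at least 2 over their whole counting interval and 84 (0.416%) a ratio of at most 0.5. Among protein-coding genes the counts were 764 higher and 37 lower. For 12956 genes the whole interval lay within 2-fold in both directions, and the middle 50% of log2 ratios ran from -0.32 to 0.39. Scaling by total counts alone shifted the median of all genes by -0.18 (log2) and raised the number of lower genes from 84 to 167. These counts describe 2 libraries and cannot separate the conditions from any other difference between them.

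The genes with the highest ratios included several known from platelets. Of 101 protein-coding genes with the whole interval above 4-fold, 21 were on the platelet marker list or a second platelet list. F13A1, the catalytic A chain of coagulation factor XIII (GRCh38 chromosome 6, 6144085 to 6321013, reverse strand), had 9447 counts in Control and 66893 in Experiment, a ratio of 5.82 (5.69 to 5.94). TUBB1, the beta-tubulin of platelets (chromosome 20, 59019254 to 59026654, forward strand), followed at 5.67 (5.55 to 5.79), from 9621 to 66411 counts. VCL, encoding vinculin, stood at 5.35, the fibrinogen receptor subunit ITGB3 at 5.30, the inhibitory platelet receptor MPIG6B at 5.32, and MMRN1, encoding multimerin, at 5.53. PEAR1, a platelet surface receptor, had a ratio of 6.09 with a lower limit of 5.43, and STON2, ABCC3, ASAP2 and TFPI lay between 5.78 and 5.87. The transcription factor gene NFIB was at 7.67 (36 and 336 counts) and SEC14L5 at 6.58. MTRNR2L12 (7.49, from 24 to 219 counts) shares sequence with the mitochondrial large rRNA and is uncertain. Only 4 genes had an interval wholly above the ratio of TUBB1, the highest of the platelet markers: F13A1, both mitochondrial rRNAs and the long non-coding RNA AC090409.2 (7 and 112 counts).

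Of the 15 protein-coding genes ranked lowest, only HDC and LTF were on a granulocyte list, and neither of their lists stood apart in the main analysis. CYP4F3, which inactivates leukotriene B4 in neutrophils (chromosome 19, 15640897 to 15662825, forward strand), had 287 counts in Control and 61 in Experiment, a ratio of 0.175 (0.130 to 0.231). HDC, the histamine-forming enzyme of basophils and mast cells, was at 0.218 (0.172 to 0.272), and LTF, encoding the neutrophil granule protein lactoferrin, at 0.195 (0.126 to 0.295). ADGRG3 was at 0.265 and the decoy interleukin-1 receptor IL1R2 at 0.307. CA1, the carbonic anhydrase of red cells, stood at 0.280 (85 and 29 counts). ARC (0.262), PGAP1 (0.316), EDN1 (0.373), HS3ST2 (0.287), BORCS7 (0.293), GPR22 (0.387), SPTBN5 (0.417) and TAF4B (0.440) completed the group with SNURF. SNURF went from 91 to 12 counts, but it lies within SNRPN, whose ratio was 1.12 (0.989 to 1.28), and is uncertain.

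**Figure D1:**
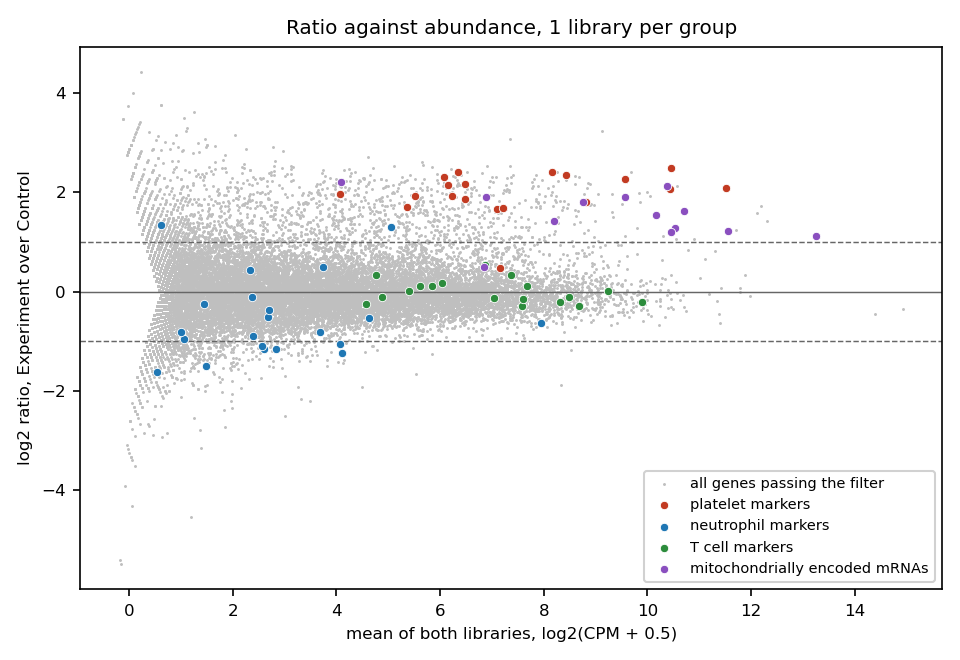
Log2 ratio of Experiment over Control (vertical axis) against the mean abundance of both libraries (horizontal axis, log2 of CPM plus 0.5), 1 grey point per gene that passed the filter, with coloured points for 4 gene lists and dashed lines at 2-fold. Platelet markers lie above the upper dashed line in 18 of 19 cases, T cell markers around 0 and most neutrophil markers below 0.

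Marker lists of 10 blood cell types described the mixture. The platelet median lay above those of all 10000 random lists. PPBP, the most abundant platelet marker, went from 23045 to 119848 counts (4.27, 4.21 to 4.33), and SELP and ITGA2B, encoding P-selectin and the alpha chain of the fibrinogen receptor, were at 5.34 and 5.08. The collagen receptor gene GP6 was the 1 platelet marker under 2-fold, at 1.40 (1.32 to 1.48). Summed over the list, platelet markers took 0.437% (exact binomial interval 0.434 to 0.440%) of Control counts and 1.69% (1.687 to 1.698%) of Experiment counts.

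B cell markers were higher in 15 of 17 cases by more than counting error and lower in 0, with a median log2 ratio of 0.73. BANK1, a scaffold of B cell receptor signalling, had the highest ratio at 3.17 (2.91 to 3.46). The B lineage factor PAX5 was at 2.05 (1.81 to 2.32) and MS4A1, encoding CD20, at 1.99. Monocyte markers had a median of 0.72 (14 of 18 higher, 2 lower). Within that list, the lysozyme gene LYZ was at 2.55 (2.41 to 2.70), and F13A1 and CD36, at 5.82 and 4.36, are also abundant in platelets. Without those 2 genes, a choice made after their values were seen, the median was 0.67, with 12 of 16 higher. Dendritic cell markers had a median of 0.77 (8 of 15 higher, 3 lower), with GZMB at 2.57, CLEC10A at 2.40, TCF4 at 1.73 and IRF8 at 1.70. In the other direction, SHD was at 0.453 (0.285 to 0.710) and SCT at 0.507. The mean of this list (0.36) did not stand apart. Cytotoxic and natural killer cell markers had a median of 0.55 (12 of 20 higher, 1 lower). GZMB, which is on both lists, and the granulysin gene GNLY at 1.76 (1.65 to 1.88) were higher, and CD8A was level at 1.02 (0.952 to 1.10).

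Neutrophil markers had a median below that of all 10000 random lists. MMP25, a membrane-anchored protease, was at 0.426 (0.359 to 0.503), KCNJ15 at 0.350, MGAM at 0.478 and MME, encoding CD10, at 0.447. The Fc receptor FCGR3B (267 and 185 counts, 0.569) and the growth factor receptor CSF3R (5003 and 3950 counts, 0.648) were also lower. The 3 higher members were PADI4, the histone-citrullinating enzyme of neutrophils, at 2.48 (2.19 to 2.81), CMTM2 at 2.63 (1.26 to 5.99) and CREB5 at 1.41 (1.17 to 1.71). Erythroid markers had a median of -0.62 but were split, with 6 of 13 lower and 5 higher, and the list did not stand apart by its mean or at 5 CPM or more. SLC4A1, the red cell anion exchanger, was at 0.434 and the haem synthesis gene ALAS2 at 0.539. On the same list TRIM58, DMTN and HEMGN, which platelets or their precursors also express, were at 3.89, 2.83 and 2.92, and the mean of the list (-0.17) was nearer to 0 than its median. Without those 3 genes, a choice made after their values were seen, the median was -0.996, though leaving out high members can only lower it. T cell markers ranged from a log2 ratio of -0.29 (BCL11B) to 0.55 (CD3E), with 5 of 18 higher and 8 lower. Plasma cell markers (0.10) and those of eosinophils, basophils and mast cells (-0.17) did not stand apart. On the latter list, which holds HDC, 3 of 9 genes were higher and 2 lower. GATA2 was at 2.33 (2.03 to 2.67) and FCER1A at 2.52 (16 and 49 counts).

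**Figure D2:**
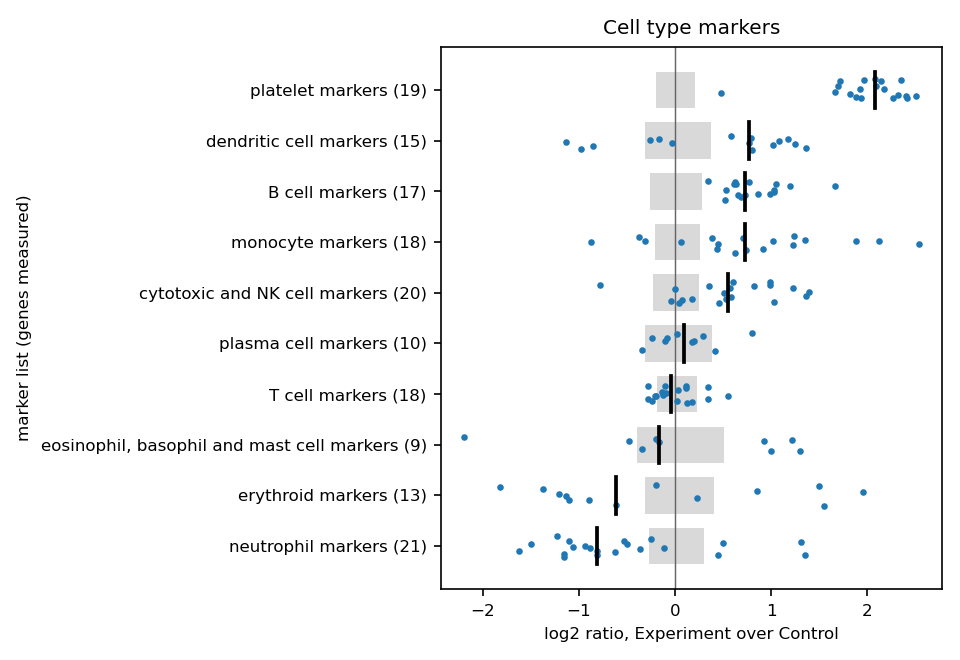
Log2 ratio of Experiment over Control (horizontal axis) of each measured gene in the 10 cell type lists, 1 blue point per gene, with the number of genes in parentheses. Black bars are list medians and grey boxes hold 95% of the medians of 10000 random lists of matched abundance. The platelet median lies at the far right and the neutrophil median at the far left, while the T cell median lies inside its box.

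Inflammatory mediators were mixed in the Experiment library, in which the platelet list had a median ratio of 4.21 and the monocyte list a median log2 ratio of 0.72. Pro-inflammatory cytokines had a median log2 ratio of 0.39, with 11 of 19 higher, 5 lower and 3 within counting error, and a mean (0.28) that did not stand apart. IFNG went from 141 to 482 counts, INHBA, encoding activin A, was at 2.12 (1.98 to 2.27), IL6 at 1.85 (1.69 to 2.01) and TNF at 1.60 (1.52 to 1.69). OSM, encoding oncostatin M, was lower at 0.575 and CSF1 at 0.598. Chemokines had a median of 0.83, with 11 of 13 higher and 1 lower. CCL5 was at 3.90 (3.79 to 4.02), CCL4, encoding MIP-1 beta, at 2.85 (2.61 to 3.12) and CXCL5 at 2.70, but platelets also carry transcripts of CCL5, CXCL5 and PPBP. CXCL8, encoding interleukin-8 and the chemokine with the second highest count in Experiment, was at 1.21 (1.19 to 1.23), from 30825 to 45414 counts. Interferons and their receptors (0.53, 8 genes) and inflammasome genes (0.31, 11 of 19 higher, 4 lower) also stood apart by their medians, the latter with IL1B, NEK7 (1.97) and CARD8 (1.93), but neither did by its mean, and the interferon list did not with no filter or at 5 CPM or more either.

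Lists that mark early signalling had medians near 0, with members in both directions. Of 33 immediate early genes, 15 were higher and 12 lower by more than counting error, with a median of -0.01. FOS was at 0.945 (0.918 to 0.972), JUN at 1.11 (1.09 to 1.14), the kinase gene SGK1 at 0.610 and NR4A1 at 1.56. The ratio of JUN was just below 1 when scaled by total counts. NF-kB feedback and target genes had a median of 0.03 (16 of 35 higher, 15 lower), with PTGS2, encoding cyclooxygenase-2, at 1.66 and NFKB2 at 0.755. T cell activation genes had a median of -0.03 (9 of 24 higher, 9 lower), with CD69 at 0.907 (0.885 to 0.930), IL2RA at 0.701 and CD40LG at 2.23. Interferon-stimulated genes lay at -0.13 (percentile 4.2) and stood apart, as lower, only by their mean (-0.08), with 8 of 43 higher and 16 lower, among them MX1 at 0.515 (0.486 to 0.545) and IFIT2 at 2.37 (2.26 to 2.49). Genes induced by interferon gamma had a median of 0.17 (percentile 95.3).

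Antigen presentation genes were higher alongside the medians of the B cell, monocyte and dendritic cell lists. MHC class II pathway genes had a median of 0.70, with 13 of 17 higher and 1 lower. HLA-DRA was at 2.15 (2.02 to 2.29), the invariant chain gene CD74 at 1.99 (1.94 to 2.05) and HLA-DMA at 2.21. MHC class I pathway genes had a median of 0.27 (12 of 18 higher, 3 lower), and B2M, at 3.02 (2.98 to 3.05), is also abundant in platelets. Oxidative stress and NRF2 target genes had a median of 0.39 (17 of 29 higher, 5 lower), with the glutathione peroxidase gene GPX1 at 3.54 (3.40 to 3.69), NQO1 at 0.506 and the haem oxygenase gene HMOX1 at 1.12 (0.896 to 1.41). Lysosome and autophagy genes had a median of 0.32 (19 of 35 higher, 10 lower), led by CTSA at 4.62 and TPP1 at 3.83. Adhesion genes (0.24, 19 of 32 higher, 6 lower) and ion channels and purinergic receptors (0.26, 16 of 32 higher, 5 lower) included genes known from platelets, ITGB3 and SELP in the first and the ADP receptors P2RY12 (5.07) and P2RY1 (3.30) in the second. In the same library the platelet markers had a median ratio of 4.21. By the mean in place of the median, the MHC class I and ion channel lists did not stand apart.

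Mitochondrially encoded mRNAs were more than 2-fold higher in 12 of 13 cases, with a median log2 ratio of 1.55, and mitochondrial transcripts together took 1.49% of Control and 3.44% of Experiment counts. MT-ND1 was at 4.37 (4.28 to 4.47) and MT-CO1, the most abundant, at 2.19 (2.171 to 2.201). MT-ND6 was the exception, at 1.41, with a lower limit of 1.32. Nuclear genes of oxidative phosphorylation had a median of 0.05 over 45 genes and did not stand apart. Replication-dependent histone genes had a median of 1.04, with 20 of 22 higher, 8 of them more than 2-fold, and 0 lower. HIST1H2BH was at 4.47 (3.91 to 5.13) and HIST1H2AC at 3.39 (3.27 to 3.51). Cell cycle genes did not stand apart (0.15, percentile 90.4). Cytosolic ribosomal proteins did, at 0.11 over 76 genes with 44 higher and 11 lower, though their median was -0.07 when scaled by total counts and their mean did not stand apart. All of these were measured beside the 4.21-fold higher platelet list.

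**Figure D3:**
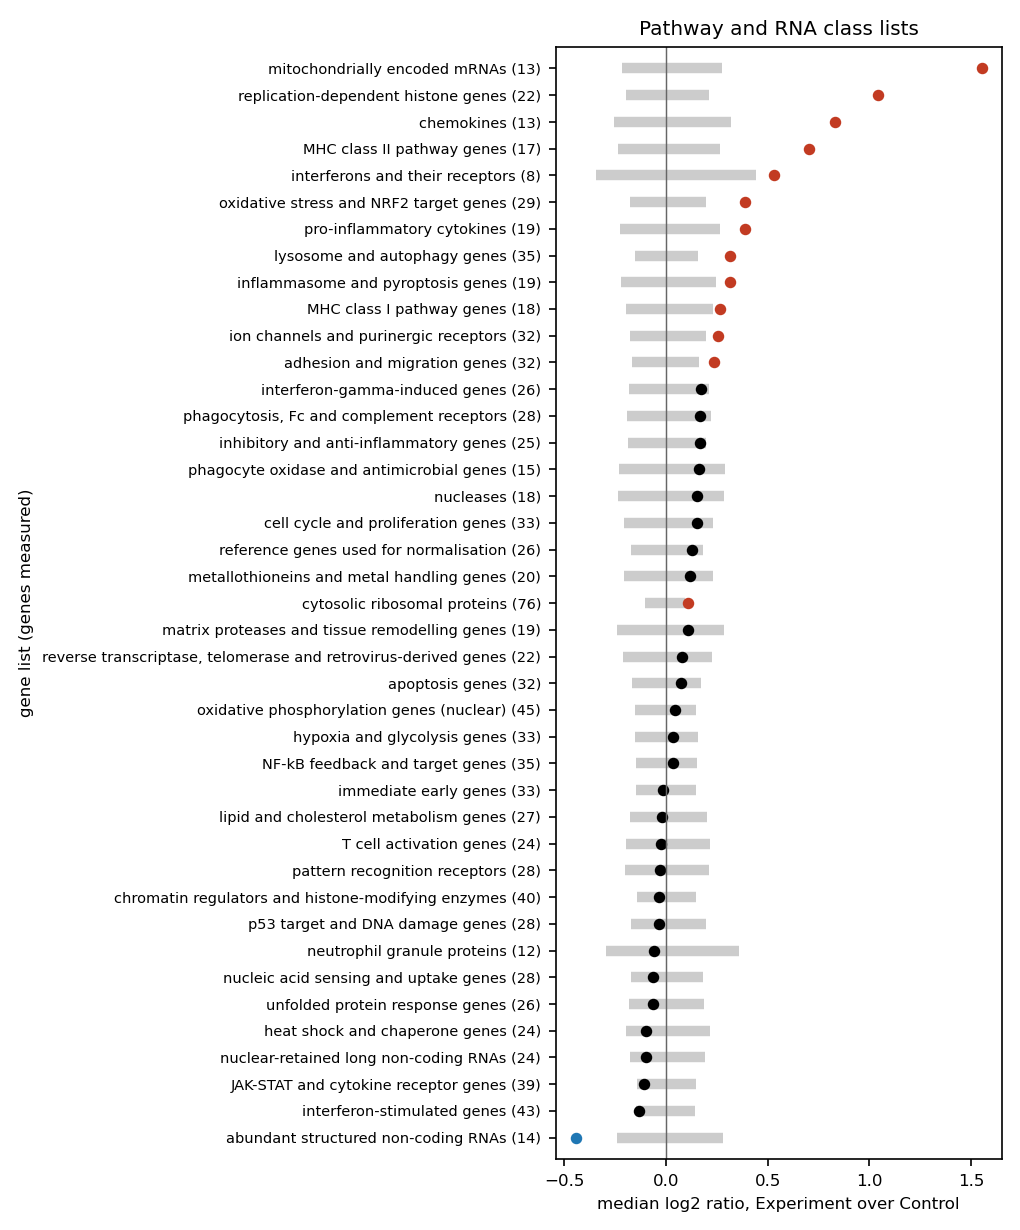
Median log2 ratio of Experiment over Control (horizontal axis) of pathway and RNA class lists, with the number of genes measured in parentheses. Points are list medians (red above, blue below and black within the 95% range of the medians of 10000 random lists, drawn as grey bars). Mitochondrially encoded mRNAs (1.55) and histone genes (1.04) lie farthest right and structured non-coding RNAs (-0.44) farthest left. The ribosomal protein median (0.11) was -0.07 when scaled by total counts.

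Other programmes had medians within their random ranges, though 3 of these lists stood apart in 1 alternative setting each, as given below. Pattern recognition receptors had a median of -0.03, but the flagellin receptor TLR5 was at 4.75 (4.20 to 5.38) and CLEC4E, a receptor for mycobacterial lipids, at 0.425 (0.331 to 0.544). Nucleic acid sensing genes (-0.07) included MAVS, the adaptor of RNA sensing, at 2.05 and IRF7 at 0.677, and nucleases had a median of 0.15. Heat shock genes had a median of -0.10, with HSPA1A at 0.974 (0.636 to 1.497) and HSPB1 at 2.76 (2.33 to 3.29). The unfolded protein response (-0.07), p53 targets (-0.04), apoptosis genes (0.08), JAK-STAT genes (-0.11), chromatin regulators (-0.03) and lipid metabolism genes (-0.02) likewise did not stand apart. JAK-STAT genes stood apart, as lower, by their mean (-0.10), and members with low ratios were the feedback inhibitors CISH (0.455) and SOCS2 (0.468). Hypoxia and glycolysis genes had a median of 0.04, yet the oxygen sensor gene EGLN3 was at 5.72 (4.31 to 7.71) and PKM at 3.38. Granule proteins of neutrophils had a median of -0.06 with members far apart, from LTF at 0.195 to LCN2, encoding lipocalin-2, at 4.16 (3.51 to 4.97), and with no filter on low counts their median was -0.68 and stood apart. Anti-inflammatory genes (0.17), phagocyte oxidase genes (0.16), Fc and complement receptors (0.17) and matrix proteases (0.11) also lay within their random ranges, but phagocyte oxidase genes stood apart at 5 CPM or more (0.29). For 8 of the 51 lists, 0 of which stood apart, the median and the mean differed in sign.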

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

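The alternatives that left out platelet genes were chosen after the results were seen. Against 987 higher and 84 lower genes, lower genes numbered 167 by total counts, 132 with no filter on low counts, 41 at 5 CPM or more and 37 among protein-coding genes, where fewer genes are counted. The interval rule at 4-fold gave 125 higher and 8 lower genes, at 1.5-fold 1685 and 403, and the ratio alone past 2-fold gave 1928 and 747. Under the other settings higher genes numbered 764 to 1031, and without both platelet lists 924 higher and 84 lower genes were counted. The latter setting leaves out only the listed genes. Of 101 protein-coding genes with the whole interval above 4-fold, 21 were on these lists. It therefore does not show how many of the higher genes reflect platelet RNA. By total counts, 775 of the 987 higher genes and all 84 lower genes stayed past 2-fold, and under DESeq2 factors all 987 and 82 did. Lists standing apart numbered 15 with means, 16 at stricter percentile limits, and 21 without the genes of both platelet lists. That last setting kept the platelet list whole and took only 1 gene from the chemokine list and 2 from the adhesion list. Genes also known from platelets, such as F13A1, CD36 and P2RY12, stayed in their lists. The number 21 therefore does not show how far the other lists reflect platelet RNA. Of 610 list values under 12 settings, 590 kept their side of the limits, 16 lost it, 4 gained it and 0 went to the opposite side. Settings that change only the scaling move a list and its random lists alike. They could hardly change the side of a list, so the values kept under them are no check on it. Those that gained it were interferon-stimulated and JAK-STAT genes by their means (-0.08 and -0.10), neutrophil granule proteins with no filter (-0.68) and phagocyte oxidase genes at 5 CPM or more (0.29). Interferons and their receptors lost it in 4 settings, ribosomal proteins, MHC class I, inflammasome, ion channel and erythroid genes in 2 each, and dendritic cell markers and cytokines in 1 each. Of 948 values of 316 named genes under 3 other scalings, 909 kept their side of 2-fold, 29 lost it, 10 gained it and 0 reversed. Total counts turned the sign of 1 list that stood apart, ribosomal proteins, and of 15 of the other 30. No paired analysis was possible because each group had 1 library. Depth limited weakly counted genes: with 100 counts over both libraries an interval ended at 1.52 times the ratio.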

Other observations

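The tests on scaling, leukocyte expression, neutrophil share and mitochondrial rRNA were chosen after the results were seen. The second platelet list and the correction for genomic span were set before their outcomes were seen, and the spread of the latter was added later. Structured non-coding RNAs were lower in the Experiment library, with a median log2 ratio of -0.44 and 9 of 14 lower by more than counting error and 0 higher. SNORD3A, the U3 RNA of ribosome assembly, was at 0.271 (0.261 to 0.282), from 10012 to 3308 counts, the spliceosomal RNU4-2 at 0.587 and RMRP, the RNA of RNase MRP, at 0.979 (0.957 to 1.00). MALAT1, the nuclear RNA with most counts in both libraries, took 3.75% of Control and 2.61% of Experiment counts, and RN7SL1, the RNA of the signal recognition particle, 2.67% and 1.73%. Beside these, platelet markers had a median ratio of 4.21, and mitochondrial transcripts took 1.49% of Control and 3.44% of Experiment counts. Long non-coding RNAs as a list did not stand apart (-0.10), with NORAD at 3.03 and NEAT1 at 1.77.

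Genes often used as references did not stand apart as a list (0.13), but single members were far from level. B2M was at 3.02 (2.98 to 3.05), ACTB at 2.68 (2.65 to 2.71), GAPDH at 2.14 (2.04 to 2.25) and YWHAZ at 2.08 (2.04 to 2.12), while POLR2A was at 0.827 (0.806 to 0.848) and TBP at 0.705 (0.589 to 0.844), in the library where the platelet list had a median ratio of 4.21. TMSB4X, encoding thymosin beta-4 and abundant in platelets, was at 3.30. ARC, which descends from a retrotransposon, was at 0.262, but the list of telomerase and retrovirus-derived genes did not stand apart (0.08). Iron handling genes as a list did not either (0.12), with the iron exporter SLC40A1 at 4.77 and NCOA4, the ferritin autophagy receptor, at 3.78.

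The platelet markers stood more than 2-fold higher in 18 of 19 cases, and 3 of the 19 are also on the chemokine or adhesion lists. A difference in depth or scaling was argued against, since a factor per library moves all genes alike and the platelet median exceeded the T cell median by 2.11 (log2). A second list of 50 platelet transcripts, written before their values were seen, had 45 members (90%) with the whole interval above 2-fold, among them VWF (4.83), RGS18 (3.96) and CAVIN2 (4.04, from 8232 to 40462 counts), which is consistent with a larger share of platelet RNA in the Experiment library. Against it, CTDSPL2 (0.732, 0.683 to 0.784) and THBS4 (0.738, 0.580 to 0.939) on that list were lower. Expression of these genes by the leukocytes themselves cannot be told apart from this, because RNA of mixed cells does not show which cells a transcript came from. Whether further Experiment libraries show the rise could not be asked with 1 library per group, and a rise from either source could recur in them. How such platelets would have entered the library was not tested. Every one of the 19 markers already had over 100 counts in Control.

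The medians of B cell, monocyte and dendritic cell markers were higher while that of T cell markers was near 0. Fewer neutrophils alone would raise all other cell types alike, but the B cell median exceeded the T cell median by 0.77 (log2), and 98.7% of pairs of a B cell and a T cell gene were in that order. This gap is part of the pattern itself and gives no separate support, and the pairs are not independent. A trend with genomic span and abundance as the whole cause was argued against too. Span includes introns, and a trend with transcript length was not tested. The Spearman correlation of log2 ratio and gene span was 0.069, but bins of span and abundance differed by up to 0.62. Removing the trend moved 22.04% of 13136 protein-coding genes by more than 0.1 (log2). After removal, the gap over 35 of 35 genes was 0.76, with 95% of gaps between lists redrawn from their members at 0.50 to 1.07. That range is a spread over genes of these 2 libraries and not over libraries. A different mixture of cells in the 2 libraries, a response of B cells and monocytes and a difference between donors all stay open and were not tested.

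The mitochondrial rRNAs MT-RNR1 (8.39, 7.84 to 8.99) and MT-RNR2 (9.47, 9.12 to 9.83) exceeded every platelet marker, the highest of which was TUBB1 at 5.67 (5.55 to 5.79). Extra platelets alone, with the same RNA in both libraries, would raise them by no more than transcripts found mainly in platelets. On the second platelet list, which was not used to find this pattern, no interval reached above 6.77, under the lower limit of 7.84. That ceiling covers the listed genes only. Outside the list, the intervals of NFIB (5.43 to 11.1) and AC090409.2 (6.17 to 33.4) reached past 7.84, with 36 and 7 counts in Control. Whether these genes come mainly from platelets was not tested. Less complete removal of rRNA in the Experiment library could also raise the mitochondrial rRNAs, since rRNA depletion kits of this type target mitochondrial rRNA too. Cytosolic rRNA, of which the rows used here held 33 and 53 counts, had a ratio of 1.32 (0.838 to 2.10), too few counts to decide, so this explanation remains open.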
